A study of Mus musculus with 9 samples.

How the data were processed

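RNA-seq was measured in 9 libraries of CD8 T cells that had infiltrated tumours of MC38, a mouse colon carcinoma line, grown in C57BL/6 mice for 15 days. Per the labels' protocols, 3 populations were collected by flow sorting on surface PD1 and on a biotin label, each in triplicate, then kept for 24 h in T cell medium with 100 IU/mL of interleukin 2. RNA came from 10000 cells per sample with a DNase step, and libraries were made with a SMART-Seq HT kit, which copies full-length cDNA by template switching. The sorted populations were PD1+Biotin+, PD1+Biotin- and PD1-Biotin- cells, with 3 libraries each. Every library was placed in its group by its label.

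The deposited tables were used as given. The authors deposited raw counts per gene, which were whole numbers in all 9 libraries. The deposited normalized signal equalled those counts divided by DESeq2 size factors, as checked against size factors recomputed from the counts. The deposited TPM values summed to the same total in each library, as TPM should. Per the submitters' processing notes, the tools were cutadapt 1.18, STAR 2.5.2a, HTSeq 0.11.0, R 3.5.1, DESeq2 1.20.0 and MultiQC, and the genome build was GRCm38. Their order, the annotation release, the strand setting and any filter were not given in the sources used here. Because the strand setting was not given, reads of a gene and of a partner that overlaps it on the opposite strand cannot be told apart, and members of near-identical families such as the Klra receptors and the granzymes Gzmd and Gzme can share reads, so single members are uncertain.

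The table held 53465 genes, with no row lacking a gene. Total counts ranged from 14409793 to 18094706 per library. Each pair of replicates differed by more than counting noise, with chi-square values per degree of freedom of 10.0 to 19.4 over genes with at least 20 counts in a pair, so no library was counted as a copy of another. Gene positions came from the GENCODE annotation of GRCm38, in which 53274 of the 53465 identifiers were found. Counting alone limited a gene with no reads in a library to 3 counts. Intervals for shares are exact Clopper-Pearson 95% intervals. These libraries carry no molecular identifiers, so intervals and floors cover counting error only.

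Gene tests used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest) on the counts of all 9 libraries with 1 coefficient per group and no further covariate, which left 6 residual degrees of freedom. The filter kept 13852 genes, which held 99.9% of the counts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the log2 fold change over the square root of the F statistic, and adjusted p-values of single genes are from edgeR throughout. Expression is given as CPM over library totals, as mean ± SD of 3 libraries. Where a group had no reads of a gene, the fold is given as a lower bound against a floor of 3 counts per library. The biological coefficient of variation was 17.9%.

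For gene groups, 33 fixed lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment was over the 33 lists within a comparison. The named genes were, per comparison, the 10 with the largest rise and the 10 with the largest fall among called genes whose libraries did not overlap between the groups and whose higher group had a mean of at least 10 CPM. Predicted genes and receptor segments were left out of these. Added to them were up to 4 members of each list with the smallest adjusted p, and a fixed set that included Pdcd1, Cd8a, Cd8b1, Tnfrsf9, Entpd1, Tcf7, Tox, Havcr2, Gzmb, Ifng and Mki67 in every comparison. The text names part of this set. Diversity of T cell receptor (TCR) beta chains was the exponential of the Shannon entropy of counts over 35 Trbv segments, after thinning every library to the lowest total of 8113 Trbv counts (mean of 100 draws), compared with exact permutation tests. The highest total was 10524.

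The groups, the comparisons, the tests, the lists, the rule for named genes and the alternatives were set before the data were examined. Alternatives were DESeq2 1.42.0, other scaling factors, other filters on low counts, the replicate number as a block, a fit on the groups compared only, limma voom, limma on log2(TPM + 1) and on log2(TPM + 0.1), a test against a fold of 1.5, removal of mitochondrial genes and receptor segments, and leaving out each library and each replicate number in turn. The labels number the replicates alike in the 3 groups. Deviations of same-numbered PD1+Biotin+ and PD1+Biotin- libraries from their group means correlated across genes at 0.103, 0.158 and 0.147, each higher than with any other number, so by the rule set for this check the numbers paired these 2 groups. The sample descriptions also give same-numbered libraries of all 3 groups a common id code. The pairing is read from the expression values, since the labels do not say what the numbers or the id codes stand for. The gene test was checked on simulated counts in which 50 well-counted genes per fold size were changed. For PD1+Biotin+ against PD1+Biotin- it recovered 56% of 1.5-fold, 86% of 2-fold and 98% of 4-fold changes over 13175 genes. For PD1+Biotin- against PD1-Biotin- the shares were 44%, 72% and 98% over 13168 genes, and for PD1+Biotin+ against PD1-Biotin- 38%, 76% and 92% over 13140 genes. No simulated change was called with the wrong sign, and 12, 9 and 8 unchanged genes were called, in the order of these comparisons. Far fewer genes were changed in the simulations than were called against PD1-Biotin- cells, so recovery in the comparisons with these cells can differ.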

Results

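Gene expression was compared among 3 sorted populations of CD8 T cells from MC38 tumours, after 24 h in culture. PD1 is an inhibitory receptor induced by T cell activation. Biotin was attached to T cells by a fucosyl transfer reaction that depends on contact with another cell, and the series title presents the label as a way to detect T cells reactive to tumour antigens. Total counts were 17270194 to 18094706 in PD1+Biotin+, 14409793 to 17333492 in PD1+Biotin- and 15097957 to 17077038 in PD1-Biotin- libraries (n = 3 each). Reads of Pdcd1, which encodes PD1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand in GRCm38), stood at 463 to 592 CPM in the 6 PD1+ libraries and at 2.11 to 5.98 CPM in the 3 PD1-Biotin- libraries. Cd8a averaged 1223 ± 153, 1326 ± 122 and 1232 ± 93.9 CPM in the same order (mean ± SD). The first principal component held 75.2% of the variance and placed PD1-Biotin- libraries at 69.1 to 73.7, PD1+Biotin- libraries at -30.1 to -23.5 and PD1+Biotin+ libraries at -48.3 to -44.0. Mitochondrially encoded transcripts made up 0.594 ± 0.031%, 0.562 ± 0.062% and 0.708 ± 0.076% of counts, again in that order. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

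Within PD1+ cells, the biotin label was accompanied by lower expression of genes of naive and memory T cells. PD1-Biotin- cells carried into the PD1+Biotin- sort could account for part or all of this, which the tests given under the other observations do not decide. Klf2, which encodes a regulator of T cell trafficking, was 9.80-fold lower in PD1+Biotin+ than in PD1+Biotin- cells (log2 fold change -3.29 ± 0.26 SE, adjusted p = 3.1e-04 by edgeR), at 1.76 ± 0.659 against 17.8 ± 5.40 CPM. Tcf7, the gene of the transcription factor TCF-1, was 5.29-fold lower (-2.40 ± 0.29, adjusted p = 0.0022). In the other direction, Tnfrsf8, which encodes the TNF receptor family member CD30, was 4.31-fold higher (2.11 ± 0.29, adjusted p = 0.0047), at 49.1 ± 8.48 against 11.7 ± 4.11 CPM. Prf1, which encodes the pore-forming protein perforin, was 1.44-fold higher (0.52 ± 0.10, adjusted p = 0.039, called in 14 of 26 alternatives).

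In all, 131 of 13852 genes were called between PD1+Biotin+ and PD1+Biotin- cells, 12 higher and 119 lower with the label. Of the 119, 78 were lower by more than 2-fold. The counts, of the higher genes above all, depended on single libraries and on the method. Without PD1+Biotin+ replicate 1, 2 or 3, 69, 206 or 58 genes were called, of which 2, 21 or 2 were higher, and without PD1+Biotin- replicate 1 or 3, 51 or 250, of which 1 or 60 were higher. Without all libraries numbered 1, 2 or 3, 20, 95 or 70 were called, of which 1, 5 or 6 were higher, and DESeq2 called 174 higher and 398 lower. Taking PD1-Biotin- RNA out of the PD1+Biotin- libraries also cut the lower calls. At shares of 3.15%, 5.17% or 8.80%, 48, 11 or 4 of 109 lower genes tested in this way stayed called, though such shares may take out too much. Besides Klf2 and Tcf7, large falls included those of Klf3 (-3.54 ± 0.38), Cd7 (-2.99 ± 0.25), Gpr15 (-2.79 ± 0.31), S1pr1 (-2.75 ± 0.33), which encodes the receptor for lymphoid organ exit, and Id3 (-2.46 ± 0.32), and at lower expression those of Trat1, which had no reads in a group and was at least 3.96-fold lower, and Trdc (-3.53 ± 0.67, called in 10 of 25 alternatives). Klra7 (-2.99 ± 0.39) and Klra6 (-2.43 ± 0.33) were among them, with the uncertainty of near-identical family members. Among called genes of at least 10 CPM, the largest rises after Tnfrsf8 were those of Batf3 (2.84-fold), a transcription factor of the AP-1 family, Neb (1.06 ± 0.17), Gcat (0.88 ± 0.14) and Tubb6 (0.83 ± 0.16). The libraries of the groups did not overlap for 18.5% of tested genes, where chance gives 10%. Tcf7 lies on chromosome 11, 52252371 to 52283014, and Tnfrsf8 on chromosome 4, 145267137 to 145315164, both in GRCm38.

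Transcripts of receptors and regulators that mark exhausted T cells were not called between the PD1+ populations when adjusted over all genes. All cells had been kept for 24 h in culture after the sort, and cells straight from the tumour were not measured. Whether the transcripts of this paragraph differed in the tumour is thus not settled. None of 15 inhibitory receptors passed (list adjusted p = 0.47 by camera), 1 lower when adjusted over the list alone, with Pdcd1 at 0.17 ± 0.16, Havcr2, the gene of TIM-3, at 0.15 ± 0.22 and Entpd1, the gene of CD39, at 0.03 ± 0.21. Tox (-0.01 ± 0.23), Tnfrsf9 (0.10 ± 0.13), Ifng (-0.27 ± 0.22), Cd8a (-0.07 ± 0.10) and Cd8b1 (-0.06 ± 0.09) did not pass either, nor did the lists of exhaustion transcription factors (adjusted p = 0.16) and of TCR activation genes (adjusted p = 0.42), each with 1 gene higher and 4 lower when adjusted over the list alone. Among 18 cytotoxic granule genes, Prf1 alone was called (list adjusted p = 0.47).

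Of the 33 lists, 16 were called by camera, 7 higher and 9 lower in PD1+Biotin+ cells, and 5 of these, all lower, were also called with an estimated correlation. Of 19 naive and memory-like genes, 9 fell and 0 rose, 16 when adjusted over the list alone (median log2 fold change -0.63, adjusted p = 8.7e-47, 0.0037 with an estimated correlation). They included Ccr7 (-1.05 ± 0.11), a lymph node homing receptor, and Nsg2 (-3.09 ± 0.35). Of 28 genes of the type I interferon response, 3 fell, 15 when adjusted over the list alone (median -0.39, adjusted p = 1.3e-12, 0.048 with an estimated correlation). These 3 were Oasl2 (-1.96 ± 0.19), Rtp4 (-1.02 ± 0.18) and Irf7 (-0.99 ± 0.17), all 3 induced by interferon. They kept the call in 26, 16 and 17 of 26 alternatives.

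Markers of 3 other cell types were also called lower, and the other lists of such markers were not called. Of 16 dendritic cell markers, 4 fell and 1 rose, 10 and 1 when adjusted over the list alone (median -0.77, adjusted p = 8.7e-10, 0.035 with an estimated correlation). Those that fell included Cd83 (-1.12 ± 0.14) and Flt3 (-1.53 ± 0.23), the one that rose was Batf3, and 2 of the 16 markers are also on other lists. Of 7 B cell markers that passed the filter on low counts, from 15 on the list, Ighm (-2.41 ± 0.31) and Cd79b (-3.29 ± 0.61, called in 13 of 26 alternatives) fell, 4 when adjusted over the list alone (adjusted p = 5.1e-07, 0.035 with an estimated correlation). Their median was -2.41, or -1.82 with the marker without reads in a group set to its bound. Of the 16 carcinoma markers on the list, only 3 passed the filter on low counts. Of these, Cdh1 (-1.35 ± 0.22) and Epcam (-1.27 ± 0.26, called in 12 of 26 alternatives) fell, both also when adjusted over the list alone (adjusted p = 3.3e-05, 0.035 with an estimated correlation). Their highest levels were in PD1-Biotin- cells, 191 ± 38.5 and 18.7 ± 5.18 CPM, and Cdh1 is also on the list of tissue residency genes.

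The 7 lists that were higher in PD1+Biotin+ cells concerned metabolism, division and protein folding, and none was called with an estimated correlation. In cholesterol synthesis, 1 of 22 genes was called, Msmo1 (0.61 ± 0.11), and 19 when adjusted over the list alone (median 0.57, adjusted p = 1.7e-20, adjusted p = 0.11 with an estimated correlation). Glycolysis genes had 0 of 18 called, 13 higher and 1 lower when adjusted over the list alone (median 0.37, adjusted p = 1.2e-09, adjusted p = 0.22 with an estimated correlation). Of the genes of mitosis, 0 of 40 were called, also when adjusted over the list alone, although 39 had a positive log2 fold change (median 0.35, adjusted p = 3.6e-13, adjusted p = 0.28 with an estimated correlation), with Mki67 at 0.51 ± 0.17. The corresponding values were 6.5e-07 and 0.25 for DNA replication, 0.0069 and 0.2 for hypoxia targets, 0.0038 and 0.36 for oxidative phosphorylation and 1.0e-04 and 0.25 for the unfolded protein response. In these 4 lists 0 genes were called (0, 2 higher and 1 lower, 0 and 2 when adjusted over each list alone, in this order). Further lists lower by camera at the preset correlation but not with an estimated one were tissue residency genes, with Xcl1 and Cdh1 called among 15 (adjusted p = 3.0e-06, adjusted p = 0.16 with an estimated correlation), NK receptors, with Klra7 and Cd7 called among 16 (0.0023 and 0.066), cytokines, with Xcl1 called among 17 (0.03 and 0.22), and the interferon-gamma response, with 0 of 23 called (0.0021 and 0.25). Adjusted over each list alone, 6, 3, 4 and 2 of their genes were lower. Median, mean and test direction differed in sign for 6 of the lists, none of them called.

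With the replicate number as a block, which the pairing of these 2 groups calls for, 231 genes were called, 61 higher and 170 lower, and 126 of the 131 remained. Genes that gained a call with the block, and in some other alternatives, included Gzmb, the gene of granzyme B, without the block 1.58-fold higher at 0.66 ± 0.20 (adjusted p = 0.16, 0.022 with the block), and Hsd17b7 (0.032 with the block) and Stard4 (0.048) of the cholesterol list, Tpi1 (0.0081), Gapdh (0.013) and Slc16a3 (0.021) of the glycolysis list and Aurkb (0.029) of the mitosis list, all higher with the label. The block also brought 2 lists past the threshold by camera, the mitochondrially encoded genes, higher (adjusted p = 0.023), and the NK cell markers, lower (0.012), of which 8 of 9 are also on another list. With an estimated correlation, without the block, these 2 lists had adjusted p = 0.61 and 0.22.

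**Figure D1:**
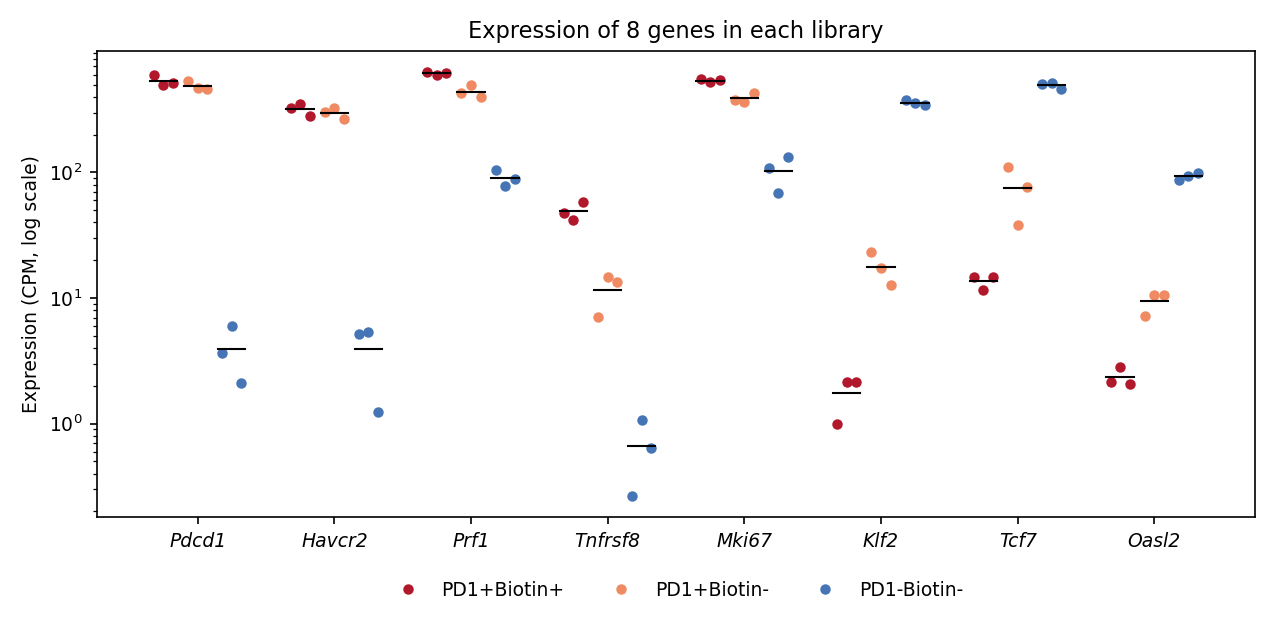
Expression of 8 genes in each of the 9 libraries, in CPM on a log axis. Each point is a library, coloured by group, and black bars are means of 3 libraries. Pdcd1 lies at 463 to 592 CPM in PD1+ libraries and at 2.11 to 5.98 CPM in PD1-Biotin- libraries, while the points of Klf2, Tcf7, Oasl2 and Tnfrsf8 separate all 3 groups.

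PD1+Biotin- and PD1-Biotin- cells, neither of which carried the label, differed in the sort marker. PD1+Biotin- cells had 134-fold more Pdcd1 mRNA (7.06 ± 0.24, adjusted p = 3.8e-09) and more of other inhibitory receptors, 81.2-fold for Havcr2 (6.34 ± 0.31), 47.1-fold for Lag3 (5.56 ± 0.20) and 15.7-fold for Entpd1 (3.97 ± 0.25). Csf1, the gene of macrophage colony-stimulating factor, was 209.8-fold higher (7.71 ± 0.32, 83.6 ± 18.6 against 0.408 ± 0.206 CPM). Klf2 was 19.1-fold lower (-4.25 ± 0.20, 17.8 ± 5.40 against 359 ± 17.1 CPM), Tcf7 6.21-fold lower (-2.63 ± 0.27) and Lef1 8.79-fold lower (-3.14 ± 0.12). The largest adjusted p of these genes was 1.2e-05 by edgeR.

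A total of 5806 genes were called, 3197 higher and 2609 lower in PD1+Biotin- cells, and libraries did not overlap for 53.6% of tested genes, where chance gives 10%. With limma on TPM the split was 2307 higher and 3758 lower, with a median shift of all genes of -0.14 on the log2 scale, so the balance of rises and falls depends on the scaling. Several of the largest rises were genes without a read in PD1-Biotin- libraries. Gzmd was at least 263-fold higher and Gzme at least 163-fold, with the uncertainty of granzyme family members, Epdr1 at least 152-fold, Gstm5 at least 115-fold and Gipc2 at least 89.9-fold. The largest falls included G0s2 (-6.45 ± 0.61), Il6ra (-5.86 ± 0.48), which encodes the interleukin 6 receptor, Slc6a19 (-5.23 ± 0.24), Tdrp (-4.99 ± 0.45) and Vipr1 (-4.97 ± 0.49).

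Of the 33 lists, 17 were called by camera, 12 higher and 5 lower, and 4 also with an estimated correlation. Of 15 inhibitory receptors, 10 rose and 3 fell, as when adjusted over the list alone (adjusted p = 1.4e-11, 0.012 with an estimated correlation), with Cd244 at 3.19 ± 0.15 and Klrc1 at 2.42 ± 0.10. Of 18 cytotoxic granule genes, 16 rose and 1 fell, as when adjusted over the list alone (median 1.57, adjusted p = 5.3e-16, 0.0074 with an estimated correlation), with Prf1 at 2.37 ± 0.11 and Gzmb at 1.57 ± 0.20. Of 19 naive and memory-like genes, 18 fell and 1 rose, as when adjusted over the list alone (median -2.32, adjusted p = 3.5e-27, 0.0074 with an estimated correlation), and the survival gene Bcl2 was at -1.45 ± 0.07. Of 12 markers of CD4 and regulatory T cells, 8 rose and 1 fell, as when adjusted over the list alone (adjusted p = 5.7e-06, 0.035 with an estimated correlation), among them Capg (2.66 ± 0.09), Ccr8 (3.64 ± 0.26) and Tnfrsf4 (2.75 ± 0.21), and 5 of the 12 are also on other lists.

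The remaining lists called by camera were lost with an estimated correlation. All 40 genes of mitosis rose (median 2.08, adjusted p = 2.3e-41, adjusted p = 0.11 with an estimated correlation), including Mki67 (2.00 ± 0.18), Nusap1 (2.34 ± 0.14) and Spc25 (2.08 ± 0.11). Similarly, 36 of 37 genes of DNA replication rose (adjusted p = 8.0e-27, adjusted p = 0.057 with an estimated correlation), including Rrm2 (2.13 ± 0.13) and Tyms (1.89 ± 0.08). Rises were also called in 13 of 18 glycolysis genes (adjusted p = 0.0071, 0.64 with an estimated correlation), 31 of 49 genes of oxidative phosphorylation (3.7e-04 and 0.32), 13 of 22 genes of cholesterol synthesis (0.0068 and 0.64) and 14 of 23 genes of the unfolded protein response (0.0066 and 0.44), such as Gapdh (0.67 ± 0.10), Cox5a (0.95 ± 0.08), Sqle (1.25 ± 0.15) and Manf (1.02 ± 0.07). Of 15 short-lived effector genes 11 rose, among them S100a4 (4.42 ± 0.19) and Cx3cr1 (3.65 ± 0.27), with adjusted p = 1.4e-06 and 0.057 with an estimated correlation. Of 15 tissue residency genes, 8 rose and 4 fell (7.8e-04 and 0.25), among them Cxcr6 (2.38 ± 0.18) and Itga1 (2.92 ± 0.15). NK receptors were called higher (adjusted p = 0.028, adjusted p = 0.14 with an estimated correlation), although 6 of 16 rose and 6 fell and both their median (-0.77) and their mean (-0.14) were negative. When adjusted over each list alone, the counts of this paragraph changed by at most 1.

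Interferon responses were lower in PD1+Biotin- than in PD1-Biotin- cells. Of 28 type I interferon genes, 17 fell and 2 rose (adjusted p = 5.7e-06, 0.15 with an estimated correlation), with Oasl2 at -3.22 ± 0.17. Of 23 interferon-gamma genes, 14 fell and 3 rose (adjusted p = 8.9e-06, 0.14 with an estimated correlation), with Iigp1 at -2.89 ± 0.14 and Gbp2 at -1.71 ± 0.12. Of 55 cytosolic ribosomal protein genes, 20 fell, 19 when adjusted over the list alone (median -0.12, adjusted p = 0.012, 0.73 with an estimated correlation). Of 7 B cell markers, 5 fell, and for these and the interferon lists the counts were the same when adjusted over the list alone (adjusted p = 0.029, 0.15 with an estimated correlation), and Ighm stood at 665 ± 47.3 CPM in PD1-Biotin- and 88.3 ± 36.5 CPM in PD1+Biotin- cells. Exhaustion transcription factors were not called as a list by camera (adjusted p = 0.11, 0.25 with an estimated correlation). They were called higher by camera with the replicate block (adjusted p = 0.025) and by fry (adjusted p = 5.5e-05), so this depends on the test. Of the 12, 6 were higher and 4 lower: Id2 (3.07 ± 0.17), Prdm1 (3.27 ± 0.35), Irf4 (1.99 ± 0.15) and Tox (2.82-fold) rose, and Eomes (-1.24 ± 0.15) fell. Tnfrsf9, the gene of the activation marker 4-1BB, rose (0.99 ± 0.13), and Ifng passed the test (0.73 ± 0.22, adjusted p = 0.02, called in 20 of 26 alternatives) with libraries that overlapped. Median, mean and test direction differed in sign for 5 lists, of which the NK receptors alone were called.

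PD1+Biotin+ and PD1-Biotin- cells differed in both markers and were the farthest apart. Pdcd1 was 150.5-fold higher in PD1+Biotin+ cells (7.23 ± 0.24, adjusted p = 2.2e-09), Havcr2 90.1-fold (6.49 ± 0.31), Tnfrsf8 80.0-fold (6.32 ± 0.39), Gzma 26.4-fold (4.72 ± 0.62) and Prf1 7.45-fold (2.90 ± 0.11). Klf2 was 187-fold lower (-7.55 ± 0.26, 1.76 ± 0.659 against 359 ± 17.1 CPM) and Tcf7 32.8-fold lower (-5.04 ± 0.31). Slc6a19, without a read in PD1+Biotin+ libraries, was at least 360.5-fold lower and Dmrta1 at least 139-fold lower. Ifng did not pass (0.45 ± 0.22, adjusted p = 0.11), and Cd8a (0.12 ± 0.10) and Cd8b1 (0.03 ± 0.09) did not either.

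In this comparison 6830 genes were called, 3611 higher and 3219 lower, and libraries did not overlap for 61.4% of tested genes against 10% by chance. Scaling to library totals gave 2866 higher and 4088 lower with a median shift of all genes of -0.16, and limma on TPM gave 2542 higher and 4527 lower with a median shift of -0.19. Of the lists, 15 were called, 10 higher and 5 lower, and the 4 that were also called with an estimated correlation were those of the previous comparison. Inhibitory receptors had 10 rises and 5 falls among 15 (adjusted p = 4.6e-08, 0.029 with an estimated correlation), cytotoxic granule genes 16 rises and 2 falls among 18 (1.9e-12 and 0.012), naive and memory-like genes 1 rise and 18 falls among 19 (2.9e-35 and 0.0094) and CD4 and regulatory T cell markers 8 rises and 2 falls among 12 (1.6e-05 and 0.034), with the same counts when adjusted over each list alone. Lost with an estimated correlation were the mitosis list, in which all 40 genes rose (adjusted p = 5.9e-42, adjusted p = 0.087 with an estimated correlation), and the DNA replication list, in which all 37 rose (3.9e-27 and 0.062), with Mki67 at 2.52 ± 0.18 and Rrm2 at 2.39 ± 0.13. The same held for cholesterol synthesis, with 20 of 22 higher (2.6e-07 and 0.32), glycolysis, with 17 of 18 higher (3.0e-05 and 0.37), oxidative phosphorylation, with 35 of 49 higher (4.7e-05 and 0.28), the unfolded protein response, with 15 of 23 higher (2.8e-04 and 0.3), and short-lived effector genes, with 10 of 15 higher (4.0e-05 and 0.082). Lower at the preset but not at an estimated correlation were the type I interferon response, with 20 of 28 lower (5.0e-09 and 0.078), the interferon-gamma response, with 15 of 23 lower (1.8e-06 and 0.093), ribosomal proteins, with 24 of 55 lower (0.019 and 0.81), and B cell markers, with 5 of 7 lower (0.0023 and 0.087). When adjusted over each list alone these counts changed by at most 1. Median, mean and test direction differed in sign for 4 lists, none of them called.

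**Figure D2:**
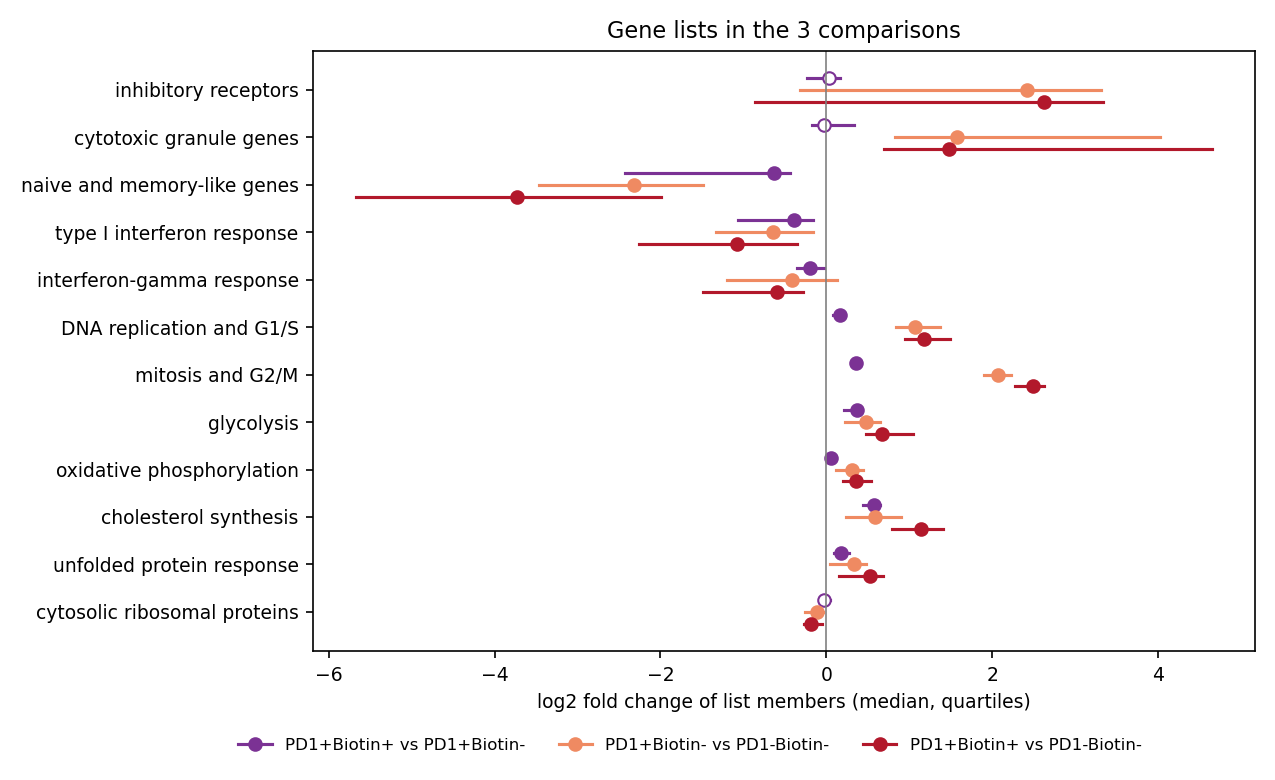
Median log2 fold change of the members of 12 gene lists (points) with quartiles (lines) in the 3 comparisons, coloured by comparison. Filled points mark lists called by camera at the preset correlation and open points lists that were not. Naive and memory-like genes have negative medians in all 3 comparisons (-0.63, -2.32 and -3.73), and inhibitory receptors have a median of 0.03 between the PD1+ groups against 2.42 and 2.63 in the comparisons with PD1-Biotin- cells.

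The populations were ordered for most genes that separated the extremes. Of the 6830 genes called between PD1+Biotin+ and PD1-Biotin- cells, PD1+Biotin- cells lay between them for 5401 (79.1%), beyond PD1+Biotin+ cells for 1372 and beyond PD1-Biotin- cells for 57. The 57 became 35 or 34 without PD1+Biotin+ replicate 1 or 3, 93 or 128 without PD1+Biotin- replicate 2 or 3, and 33, 27 or 31 without PD1-Biotin- replicate 1, 2 or 3. Simulated PD1+Biotin- libraries equal to either of the other groups lay between for 50.01% and 49.0%. PD1-Biotin- cells carried into the PD1+Biotin- sort, which the other observations leave open, would also place these libraries between. The order was not set beside a simulated mixture, so it cannot tell such cells from a difference between the populations. The median position was 81.7% of the way from PD1-Biotin- to PD1+Biotin+ cells (quartiles 64.9% and 95.9%). Of the 119 genes lower in PD1+Biotin+ than in PD1+Biotin- cells, such as Klf2, Tcf7 and Oasl2, 109 were also called lower in PD1+Biotin+ than in PD1-Biotin- cells, 1 was called higher and 9 were not called. All 12 genes higher with the label, such as Tnfrsf8 and Prf1, were also called higher than in PD1-Biotin- cells. Of all tested genes 23.2% were called lower and 26.1% higher there, and as both comparisons use the same PD1+Biotin+ libraries, part of this sharing of direction may come from them. Both PD1+ groups shared 5245 calls of the same direction against PD1-Biotin- cells, 2933 higher and 2312 lower, with 0 of opposite direction. Independent lists of these sizes would share 833 and 606, a value without the shared controls, and 20 simulations of unchanged groups against the same libraries gave 0 shared calls, a value without real effects, so neither excess measures a shared effect. Part of the excess may come from the shared PD1-Biotin- libraries.

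Use of TCR beta variable segments was narrower in both PD1+ groups than in PD1-Biotin- cells. The effective number of Trbv segments was 10.8 ± 0.57 in PD1+Biotin+, 10.9 ± 0.79 in PD1+Biotin- and 15.6 ± 0.05 in PD1-Biotin- libraries (mean ± SD, n = 3). Each PD1+ group lay below all PD1-Biotin- libraries (differences of -4.79 and -4.67, exact permutation p = 0.1 each, 0.15 adjusted over the 3 comparisons), and 0.1 is the smallest p that 3 against 3 libraries allow. The PD1+ groups differed by -0.12 (exact permutation p = 0.9), and the sign of this difference changed when PD1+Biotin+ replicate 2 or PD1+Biotin- replicate 1 or 3 was left out (0.179, 0.0612 and 0.153).

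Some segments in high use were shared by PD1+ libraries and others differed between them. Trbv16 was high in all 6 PD1+ libraries, at 16.2% to 33.1% of Trbv counts against 8.01 to 9.74% in PD1-Biotin- libraries, with 33.1% (95% interval 32.1 to 34.0%) and 26.6% (25.7 to 27.5%) in replicate 2 of PD1+Biotin+ and PD1+Biotin- cells and 25.1% (24.1 to 26.0%) in PD1+Biotin- replicate 1. Trbv1 took 23.2% (22.4 to 24.0%) and 21.2% (20.4 to 22.0%) in replicate 3 of the PD1+ groups and 1.24% to 7.00% in the other PD1+ libraries. Trbv13-1 took 22.9% (22.1 to 23.8%) and 17.6% (16.8 to 18.5%) in replicate 1 and 7.18% to 9.40% in the other PD1+ libraries. Trbv2 took 15.4% (14.7 to 16.1%) and 21.4% (20.6 to 22.2%) in replicate 2 and 0.940% to 2.04% in the other PD1+ libraries, against 2.31 to 4.36% in PD1-Biotin- libraries. In PD1-Biotin- libraries Trbv12-2 led with 14.4 to 15.1%.

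**Figure D3:**
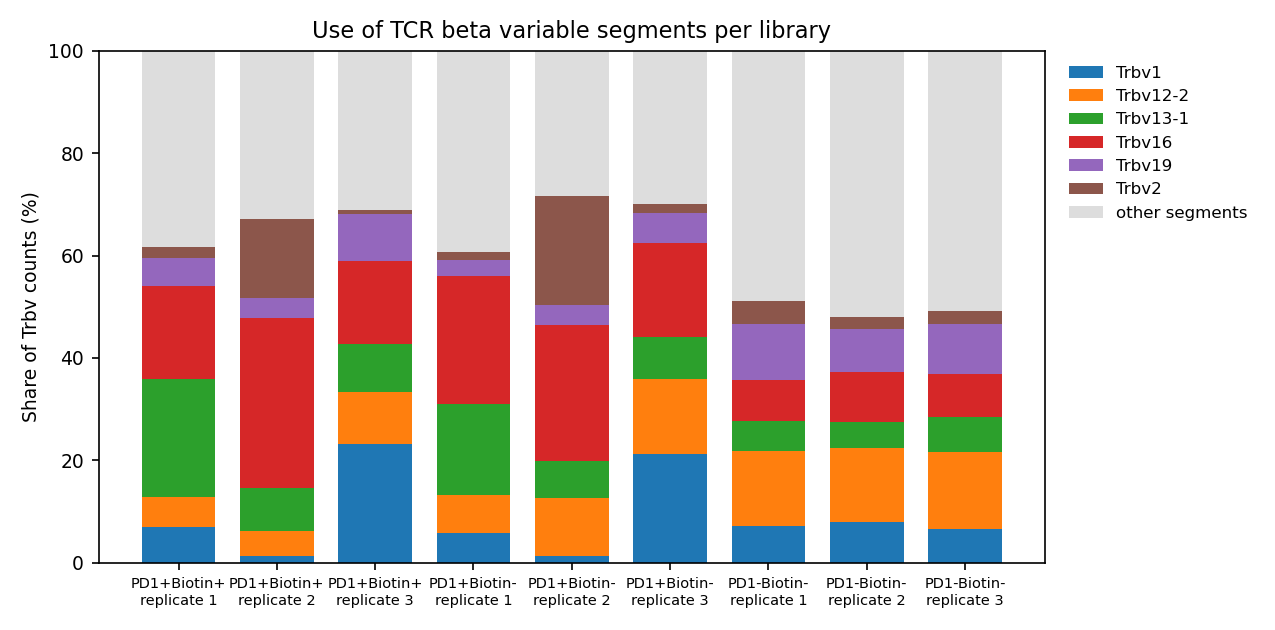
Share of Trbv counts, in percent, taken by 6 TCR beta variable segments in each of the 9 libraries, with the other segments in grey. Trbv2 reaches 15.4% and 21.4% in replicate 2 of the PD1+ groups, and Trbv1 reaches 23.2% and 21.2% in replicate 3.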

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

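No alternative given here was chosen after results were seen. Between PD1+Biotin+ and PD1+Biotin- cells the 131 calls became 572 with DESeq2, 759 without a filter on low counts, 230 with a stricter filter, 231 with the replicate block, 68 with only the libraries of these groups, 85 with limma voom, 39 with limma on unfiltered TPM and 40 against a fold of 1.5, the last by construction. Leaving out libraries gave from 20 to 250. The causes were not tested, and the reduced fits also had fewer samples. DESeq2 and the fit without a filter each kept all 131 genes and added others. Of 35 genes named as called in this comparison, 5 were called under all of 26 alternatives, 30 lost the call in some and 0 changed sign. Prf1 kept its call in 14 of 26, with adjusted p from 2.4e-06 to 1, and Klf2 in all 26. Calls were also kept in 15 of 26 for Tubb6, 13 for Msmo1 and Cd79b, 12 for Epcam and 10 of 25 for Trdc. Against PD1-Biotin- cells the test against a fold of 1.5 left 2233 of 5806 and 3015 of 6830 calls, and the other counts stayed within 1.5 times. There 66 of 69 and 38 of 39 named calls held in every alternative. Called lists fell from 16, 17 and 15 to 5, 4 and 4 with an estimated correlation, and fry gave 7, 25 and 23. The replicate block gave 5892 and 6859 calls against PD1-Biotin- cells, whose numbers did not pair with those of the PD1+ groups (correlations -0.019 to 0.102). Under that block Cd8a was called in PD1+Biotin- cells, Ifng in PD1+Biotin+ cells, and 2 and 1 further lists. These were exhaustion transcription factors (higher) and mitochondrially encoded genes (lower) in PD1+Biotin- cells, and carcinoma markers (lower) in PD1+Biotin+ cells. In that block the sign-flip p of segment diversity had a smallest value of 0.25. The shared calls (5245) and ordered genes (5401) stayed within 1.5 times. Segment diversity between the PD1+ groups (-0.12) ranged from -0.573 to 0.179 over left-out libraries and was positive in 3 cases (0.179, 0.0612 and 0.153), and the cause was not tested. At this depth 1.5-fold changes were recovered in 56% of simulated genes between the PD1+ groups, so smaller differences can be missed.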

Other observations

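The tests of carried-over cells, dendritic cells, B cells and shared segment use were chosen after the results they address had been seen, and the counts over other splits of the libraries before. Transcripts of the gamma-delta TCR moved in both directions, and their list of 7 markers, with 2 higher and 3 lower, was not called in PD1+Biotin- (adjusted p = 0.86 by camera) or PD1+Biotin+ cells (0.87) against PD1-Biotin- cells. Tcrg-C2 was higher in PD1+Biotin- (1.48 ± 0.17) and in PD1+Biotin+ (1.83 ± 0.18) than in PD1-Biotin- cells, at 314 ± 57.3, 389 ± 104 and 119.5 ± 8.42 CPM, and so was Trgv2 in PD1+Biotin- cells (1.41 ± 0.17), while Tcrg-C1 (-1.56 ± 0.31) and Tcrg-C4 (-1.02 ± 0.21) were lower there. Trdc, the constant segment of the delta chain, was lower in PD1+Biotin+ than in PD1-Biotin- cells (-5.49 ± 0.67, 0.431 ± 0.380 against 21.7 ± 4.57 CPM). The gamma constant segments are near-identical copies, so single ones are uncertain.

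The chemokine genes Xcl1 and Ccl3 fell while Csf1 (7.81 ± 0.32 between PD1+Biotin+ and PD1-Biotin- cells) rose. Xcl1, the gene of lymphotactin, was lower in PD1+Biotin+ cells than in PD1+Biotin- (-1.97 ± 0.35) and PD1-Biotin- cells (-4.32 ± 0.36), and Ccl3 was lower in PD1+Biotin+ than in PD1-Biotin- cells (-2.63 ± 0.25, 7.21 ± 0.888 against 48.8 ± 15.7 CPM). The list of p53 targets and apoptosis genes went both ways between PD1+Biotin+ and PD1-Biotin- cells, with 6 of 16 higher and 5 lower, and was not called (adjusted p = 0.61 by camera). Of its genes, Bcl2l11, which encodes the pro-apoptotic protein BIM, was at -0.75 ± 0.10 between the PD1+ groups and at -1.60 ± 0.10 between PD1+Biotin+ and PD1-Biotin- cells, and the anti-apoptotic Bcl2, which is not on that list, was at -1.76 ± 0.07 in the latter comparison.

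The genes lower in PD1+Biotin+ than in PD1+Biotin- cells might reflect PD1-Biotin- cells carried into the PD1+Biotin- sort, but 10 of the 119, among them Cd83 and Flt3, were called higher in PD1+Biotin- cells than in both other groups, which a mixture of these cannot give. For the other 109, each of 53 reference genes gave an upper limit on the share of PD1-Biotin- RNA, from 0.098% to 25.9%. These limits hold for carried-over cells of the mean PD1-Biotin- profile. Taking out 3.15%, 5.17% or 8.80%, the 10th percentile, lower quartile and median of the limits, left 48, 11 or 4 called. The median log2 fold change shrank from -1.37 to -1.21, -0.95 or -0.72 (median SE 0.23 before and 0.24, 0.24 and 0.31 after). As these shares exceed the limits of part of the reference genes, some calls may be lost by taking out too much. How many calls carry-over explains is thus not settled. The share was then left free in each PD1+Biotin- library. Of the 109 genes, 27.5% (23 below and 7 above) departed from a mixture of the other groups. Of the 53 reference genes fitted alike, 15.1% departed. In 20 simulated mixtures at most 0.712% of 281 to 317 genes and 3.77% of the reference genes departed. By the rule set before this test was run, the 27.5% counts against cells of the mean PD1-Biotin- profile as the only cause. Real reference genes, which such a mixture should fit as well, also departed more often than in any simulation. Either they too go against the mixture, or the simulations understate its misfit. The test cannot tell these apart, so it does not settle whether cells of the mean PD1-Biotin- profile are the only cause. A part played by them, or cells of another profile, cannot be told apart from a difference between the PD1+ populations either. For the 12 higher genes, dilution by carry-over is argued against at the 3.15% share only, with a smallest fold of 1.22 against a dilution of 1.03. The shares fitted freely were larger and no dilution was calculated for them, so dilution is not settled at those shares. At the highest limit, 25.9%, the dilution of 1.35 exceeds that smallest fold. That share, however, lies above the limits of all other reference genes. For the 10 genes, dendritic cells are a candidate source that a sort of CD8 T cells should remove, with a median log2 fold change of -0.77 for Cd74, H2-Aa, H2-Ab1 and H2-Eb1, none of them called and H2-Aa, H2-Ab1 and H2-Eb1 highest in PD1-Biotin- cells, which leaves it open beside a difference in the T cells.

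PD1+ libraries of the same replicate number shared their Trbv use. The dissimilarity of segment shares was 13.5% between same-numbered PD1+Biotin+ and PD1+Biotin- libraries (11.9 to 14.9%) and 37.3% between others (31.6 to 42.2%), the closest of the 6 possible matchings. For PD1+Biotin- with PD1-Biotin- libraries 5 of 6 matchings were as close. This could not show a pairing, because the PD1-Biotin- libraries were nearly alike in segment use (dissimilarity 5.73 to 7.50%). Cells of one PD1+ sort carried into the other are argued against, since the most that Batf3 and Klf2 allow would bring unmatched libraries to 20.4%, above the highest matched value of 14.9%, and 63.7% would be needed. Origin of same-numbered sorts from the same tumours remains a hypothesis, untested because the labels do not say what the numbers or the common id codes stand for.

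Ighm, an immunoglobulin gene, stood at 665 ± 47.3 CPM in PD1-Biotin- cells and at 16.1 ± 5.33 CPM in PD1+Biotin+ cells, which might come from B cells in the PD1-Biotin- sort. B cells would bring Igkc and Cd79a, but the higher of these reached 0.150% of the Ighm level and Cd79b reached 1.90%, and Ms4a1 and Pax5 had no reads in PD1-Biotin- libraries. B cells as the source are thus argued against, and transcription of the heavy chain locus in T cells stays as an untested hypothesis.

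For the counts of called genes, the real grouping was the 1 of 10 splits of 6 libraries with the highest count in each comparison (131, 5806 and 6830 against a highest other of 0). Called lists numbered 16, 17 and 15 against a highest other of 13, 15 and 12. With 10 splits no share under 0.05 can be reached. Every other split also puts libraries of both populations into each group, so that a real difference widens its spread and lowers its count. The contrast with 0 therefore cannot show how many genes chance would call.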
